A study of Homo sapiens with 2 samples.

How the data were processed

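RNA was measured in 2 libraries of HTR8/SVneo cells, 1 infected with a control hairpin lentivirus and 1 with a hairpin against ALKBH5. Per the labels' protocols, total RNA was extracted with Trizol and libraries were built with the Illumina TruSeq RNA kit. Reads were placed with Bowtie 0.12.2 on hg19 per the submitters' processing notes. The gene counter, its use of strand, the normalization tool and the test were not given in the sources used here. For 603 of 631 rows, the deposited gene coordinates equal those of GENCODE release 29 on GRCh38, a build other than the hg19 of the notes. Coordinates printed here are the deposited ones with the GRCh38 annotation.

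The deposited signal columns, 1 per library, hold gene read counts that the authors scaled by 1 factor per library, as inferred from the evenly spaced values. The deposited log2 fold change of each gene matched the log2 ratio of both columns with 0.125 added, within 0.01, for 630 rows. The deposited p-value and adjusted p-value of each gene are those of the authors' own comparison of 1 library with 1 library, and 630 of them matched an exact negative binomial test at a fixed dispersion of 0.04 within 1%. All deposited p-values were under 0.05 and the smallest absolute log2 fold change was 0.83, so the table is a selected list. The adjusted values imply that 24962 genes had been tested. If no gene differed and p-values were evenly spread, a limit of 0.05 would pass more than 631 of 24962 genes. Exact p-values of sparse counts are not evenly spread, and the sparsest genes cannot pass the limit. Fewer unchanged genes may therefore pass than this count gives. The length of the list alone was not taken as evidence of differences between the libraries.

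The step of each column was fitted from its lowest values upwards, and 1 step was taken as 1 read. The steps gave the ratio of the shControl to the shALKBH5 scaling factor. It equals the depth ratio of shALKBH5 to shControl only if the authors scaled by depth. The steps also gave the reads behind each value and exact conditional binomial 95% intervals for ratios. These intervals leave out biological and library variation, and reads without molecular identifiers are not independent molecules. They also take no account of the selection of the list by p-value. An interval that leaves out 1-fold is therefore no separate evidence of a difference, and folds of selected genes may be overstated. A gene at 0 in 1 library was given a bound computed from 3 reads in that library, which takes the other value without its counting error, and the exact lower limit is printed beside it. Gene identifiers were named through a gene name table (618 of 631) and matched to GENCODE 29 (624), and 7 had no name in either. Where a name had several rows, the row with the highest mean stood for the gene, which left 627 genes after 4 rows of 2 names were merged.

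Gene lists, the pseudocount, the floors, the rule for named genes and most alternatives were fixed before the data were examined. The design foresaw raw counts or depth-normalized values such as CPM, and the table held scaled counts, so the pseudocount of 1 and the floor of 1 were applied in scaled counts and the floor for named genes was 50. With 1 library per group no test between groups was run, and genes were counted by size at 2-fold. Named genes were ALKBH5 and its list, CCN1, the 12 largest log2 ratios in each direction among genes with a name that does not start with SNORA, SNORD, SCARNA, RNU or MIR, and up to 4 members of each of 26 fixed lists by size, or the 2 most abundant where none reached 2-fold. The exclusion of short non-coding RNAs by these name starts left the transfer RNA gene MT-TN in. Further members named to complete a list's count, the genes of the authors' deposited adjusted calls, and genes in the closing section outside this rule were chosen after their values were seen. A list with at least 5 listed members was described by its median log2 ratio and its percentile among 10000 random lists of the same size, drawn from the listed genes within 10 bins of mean expression. Of all list symbols 6 matched no gene.

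Near-identical copies were searched with BLAST+ 2.17.0 by aligning the longest transcript of each gene to all GENCODE 29 transcripts of other genes, at 98% identity over 80% of its length. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps, size rule and percentiles were tested on simulated data for this comparison with 631 genes. All 3 planted exchanged rows were found with 0 others. Of 200 genes simulated at 4-fold, 90% passed 2-fold, and 100% of those with a larger mean of 50 or more did. Of unchanged genes 13.2% passed 2-fold by counting noise, and 0% of those with a mean of 50 or more. These simulated genes had no spread between libraries and were not selected by p-value, so both shares may be higher in the selected list. A planted list of 8 genes reached percentile 99.9. Alternatives covered the pseudocount, scaling, floors, thresholds, duplicate names, random lists without matching, and, added after the data were seen, a floor of 50, genes at 0 set to their bound, the short non-coding list without microRNA host genes, and the counts without COL1A1, COL1A2 and SMAD5 or without genes that have a near-identical copy.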

Results

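Gene expression was measured by RNA sequencing in HTR8/SVneo cells, an immortalised line of human placental trophoblast, after infection with a lentivirus carrying a short hairpin RNA against ALKBH5 (shALKBH5) or a control hairpin (shControl). Each group held 1 library, so no difference below had a replicate check, and the intervals cover counting error only. Genes were listed by p-value first, so intervals that leave out 1-fold follow from the selection. The table analysed was a list of 631 rows that the authors had already selected, with p-values of 0.0494 or less in the authors' deposited table. It held 627 differently named genes, and genes outside it were not analysed here. With evenly spread p-values, a limit of 0.05 would pass more than 631 of 24962 unchanged genes, the number the authors tested. Fewer may pass in practice, since p-values of sparse counts are not evenly spread. A place in the list was not taken by itself as evidence that a gene differs. The listed genes carried 49837 reads in the shALKBH5 library and 58344 in the shControl library, taking 1 step of each column as 1 read. Total library depth was not given in the sources used here. By the spacing of the values, the scaling factor of shControl stood at 1.013 times that of shALKBH5. Values are scaled read counts as deposited, folds are ratios of these values, and log2 ratios were taken after adding 1 to both values.

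The comparison of both libraries addressed which transcripts differ in trophoblast cells when ALKBH5 is knocked down. ALKBH5 encodes a demethylase that removes N6-methyladenosine from RNA, and its transcript was lower in the shALKBH5 library, at 2680 scaled counts against 5187 in the shControl library. The level was 51.7% of the shControl level (95% counting interval 49.3 to 54.1%) and the log2 ratio was -0.95, with 2698 and 5153 reads behind the values. The gene (ENSG00000091542, protein-coding) lies on chromosome 17 from 18183078 to 18209954 on GRCh38, and the gene AC087164.1 overlaps it on the opposite strand. In the authors' deposited table the p-value for ALKBH5 was 0.0218 and the adjusted p-value was 1. ALKBH5 was the 1 listed member among the 23 fixed genes of the N6-methyladenosine machinery, which also include the demethylase FTO, the methyltransferases METTL3 and METTL14 and the YTH domain readers. CCN1, named in advance as a gene of interest, was not analysed here. The direction for ALKBH5 turned (log2 ratio 0.58) when the shALKBH5 column was rescaled to give the listed genes a median log2 ratio of 0, a rescaling that takes its reference from selected genes alone. It raised log2 ratios by up to 1.53, by less for sparse genes and by 0 for genes at 0 in the shALKBH5 library. Abundant genes with log2 ratios between -1.53 and 0, ALKBH5 among them, therefore turn by construction, which is no test of a scaling error.

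Genes higher in the shALKBH5 library, among those with a value of at least 50, included transcription factors, a chaperone and a phosphatase. FOSB, a subunit of the AP-1 transcription factor, was 3.95-fold higher (63.6 against 16.1; interval 2.26 to 7.32), with ERCC1 overlapping it on the opposite strand, and DUSP2, a phosphatase that inactivates MAP kinases, was 3.22-fold higher (146 against 45.3; 2.29 to 4.61). HSPA1A, an inducible HSP70 chaperone, was 3.34-fold higher (383 against 115; 2.70 to 4.15). TNFSF9, the ligand of the costimulatory receptor 4-1BB, was 2.56-fold higher (453 against 177; 2.14 to 3.06), and SNAI1, a transcriptional repressor of E-cadherin, was 2.60-fold higher (99.3 against 38.3; 1.77 to 3.88). The 12 higher genes leave out short non-coding RNAs by name, and SERF1B had the largest log2 ratio among them as deposited (124 against 15.1, 8.22-fold, interval 4.80 to 15.1). Its transcript has a near-identical copy in SERF1A, so its value is uncertain. COL1A2, whose direction is uncertain, would rank above SERF1B if its values (5.03 against 50.7) were exchanged between the columns. The mitochondrial transfer RNA gene MT-TN stood at 463 against 122 (3.80-fold; 3.11 to 4.68). The divergent transcript BTG1-DT (68.5 against 18.1), LY6G5C (59.6 against 21.1), the readthrough gene RNF103-CHMP3 (50.7 against 19.1) and the histone genes H2BC11 and H3C8 completed the 12 genes named by the fixed rule. BTG1-DT overlaps BTG1 on the opposite strand and RNF103-CHMP3 overlaps CHMP3 and RNF103 on the same strand, so their values are uncertain.

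BOLA2B had the lowest log2 ratio among named genes with a value of at least 50. It stood at 18.9 against 282 (log2 ratio -3.83; 14.9-fold lower, interval 9.38 to 25.2), and its transcript has a near-identical copy in BOLA2, which leaves its value uncertain. CDK15, a cyclin-dependent kinase gene, was 6.50-fold lower (11.9 against 77.5; 3.52 to 13.1). PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, was 4.15-fold lower (21.9 against 90.6; 2.58 to 6.94), CARF was 3.69-fold lower (27.8 against 103) and MCTP1 3.25-fold lower (37.7 against 123). CBS, which makes cystathionine from homocysteine and serine, stood at 96.4 against 278, and its near-identical copy CBSL leaves its value uncertain. BCAN (22.8 against 67.4) encodes the proteoglycan brevican, and the non-coding genes LINC00920 (13.9 against 51.3), CIRBP-AS1 (20.9 against 71.5) and DOCK9-DT (17.9 against 58.4) were lower too. CIRBP-AS1 lies opposite to CIRBP, CARF to WDR12 and MCTP1 to SLF1, and whether counting used strand was not given in the sources used here. Of the 50 genes named by the fixed rule, 23 overlap a gene on the opposite strand, and reads of such pairs could not be told apart. COL1A2 (5.03 against 50.7) and SMAD5 (410 against 2159) also ranked among the 12, but both have values that do not lie on the step of their own column, so their direction is uncertain. Of these 12 genes, CBS alone passed 0 under the rescaling to the listed genes' median, with a log2 ratio of 0.00.

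In all, 188 of the 627 listed genes were higher in the shALKBH5 library and 439 were lower, and 163 were at least 2-fold higher and 421 at least 2-fold lower. Protein-coding genes made up 262 of them, with 69 higher and 193 lower, and the other 365 genes had 119 higher and 246 lower. Rescaling to the listed genes' median gave 188 at least 2-fold higher and 176 at least 2-fold lower. Most listed genes were sparse: the median of the larger value was 18.9, a value of 0 stood in 104 rows for shALKBH5 and in 49 for shControl, and with a floor of 50 the counts at least 2-fold higher and lower were 43 and 70.

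**Figure D1:**
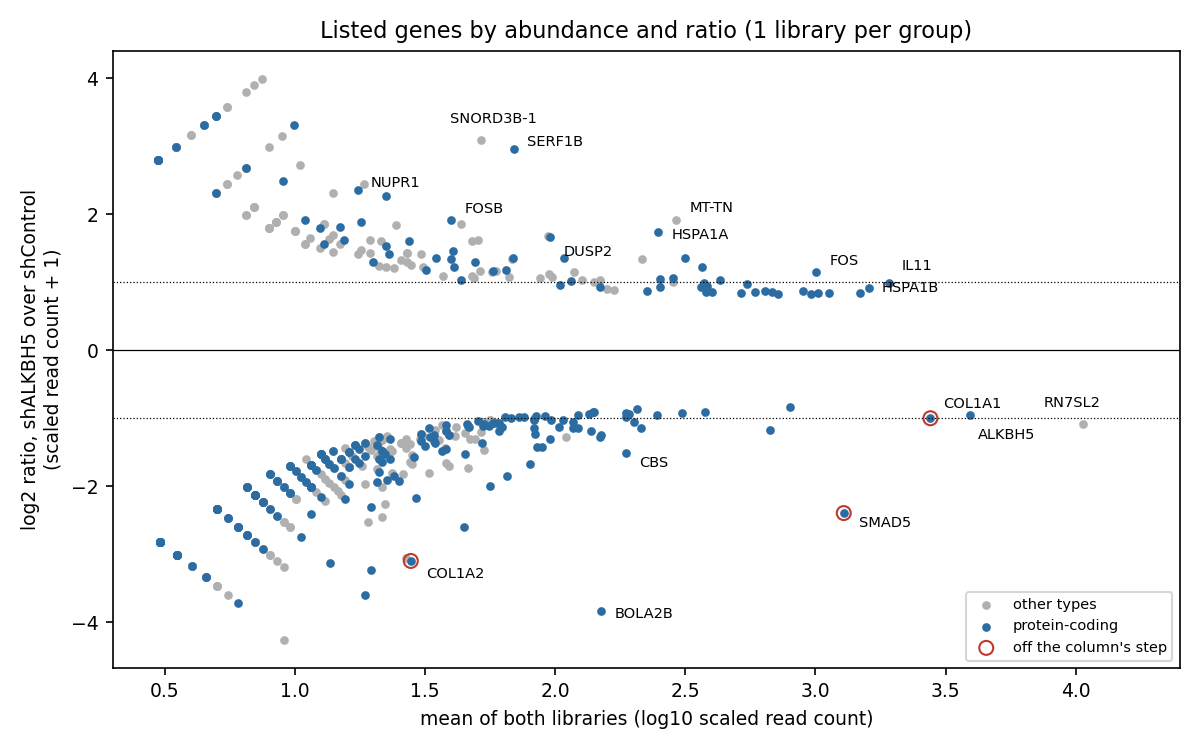
Each point is 1 listed gene, with the mean scaled read count of both libraries on a log10 axis and the log2 ratio of shALKBH5 over shControl after adding 1. Dotted lines mark 2-fold, blue points are protein-coding genes, gray points are other types, and red rings mark the 3 genes whose values lie off their column's step. The empty band around 0 reflects the selection of the list. ALKBH5 lies at -0.95, or at 0.58 when rescaled to the median of these selected genes, which turns it by construction.

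Immediate early genes, which are transcribed within minutes of a stimulus, had 6 listed members of 40. All 6 were higher in the shALKBH5 library, 4 of them at least 2-fold. Besides FOSB and DUSP2, FOS was 2.23-fold higher (1390 against 623; interval 2.03 to 2.46), the stress-responsive factor ATF3 2.07-fold (340 against 164; 1.71 to 2.51), the nuclear receptor NR4A2 1.96-fold (720 against 367; 1.73 to 2.23) and SPRY4, an inhibitor of receptor tyrosine kinase signalling, 1.92-fold (477 against 249; 1.64 to 2.25). Their median log2 ratio of 1.10 lay at percentile 98.1 among 10000 random lists of 6 listed genes matched on mean expression, 95% of which had medians between -1.16 and 1.08. Against lists not matched on expression the percentile was 94.9. FOS, NR4A2, SPRY4 and ATF3 had means above 200, where 30 of 42 listed genes were higher, against 10 of 28 at means of 100 to 200. The top bin of the matching mixes both ranges, so both percentiles may be raised by this lean. SPRY4 is overlapped on the opposite strand by SPRY4-AS1.

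Replication-dependent histone genes, which supply chromatin during S phase, had 5 listed members of 56. H2BC11 (156 against 60.4; 2.58-fold, interval 1.91 to 3.54), H3C8 (57.6 against 22.1; 2.60-fold), H4C8 (70.5 against 28.2; 2.50-fold) and H2AC6 (291 against 159; 1.83-fold) were higher in the shALKBH5 library. H2BC13 had 0 against 9.06 and was at least 3.04-fold lower by the bound of 3 reads, with an exact 95% lower limit of 2.0-fold when the counting error of both values is included. The median log2 ratio was 1.29 and the mean 0.30, and the median lay at percentile 96.4 of matched random lists, whose 95% range of -1.48 to 1.34 includes it.

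Extracellular matrix genes had 5 listed members of 50. LAMA4, a laminin chain of basement membranes, was 2.34-fold higher (44.7 against 19.1), and DCN, the proteoglycan decorin, had 5.96 against 0 and was at least 1.97-fold higher by the bound of 3 reads (exact lower limit 1.16-fold). COL4A3, a collagen chain of basement membranes, was lower at 1.99 against 12.1 (6.08-fold; interval 1.35 to 55.9). COL1A1 (1843 against 3687) and COL1A2 (5.03 against 50.7), the chains of type I collagen, were lower as deposited, but the values of both genes fall on the step of the opposite library's column, so their direction is uncertain. The median log2 ratio of the list was -1.0 (percentile 76.8), and it turned to 1.18 without COL1A1, COL1A2 and SMAD5 and to 0.53 under the rescaling to the listed genes' median.

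The fixed name patterns for small nuclear, nucleolar and other short non-coding RNAs took 25 listed genes, 10 higher and 15 lower in the shALKBH5 library. They also took 3 long microRNA host genes (MIR762HG, MIRLET7IHG and MIR133A1HG), all 3 of them lower, and the 22 genes without these were 10 higher and 12 lower. U3 small nucleolar RNA genes, which guide early processing of ribosomal RNA, were among those higher, with SNORD3B-1 at 93.4 against 10.1, SNORD3A at 76.5 against 24.2 and SNORD3C at 14.9 against 0 (at least 4.93-fold higher by the bound of 3 reads, exact lower limit 3.54-fold). Reads of these near-identical copies could not be told apart. RN7SL2, an RNA component of the signal recognition particle, was 2.13-fold lower at 6830 against 14515, though higher (0.44) under the rescaling to the listed genes' median, and its near-identical copies, RN7SL1 among them, leave its value uncertain. The small RNA genes RNU6-623P (7.95 against 0) and MIR4305 (0 against 10.1) lie opposite to PPM1D and COG6. The median log2 ratio of the 25 genes was -1.60 (percentile 82.8, or 40.5 among lists not matched on expression), which is the value of MIRLET7IHG, and -1.09 with genes at 0 set to the bound of 3 reads. Without the 3 host genes the median was -1.46 (percentile 91.1, or 60.9 without matching) and the mean -0.09. Under the rescaling to the listed genes' median, the list's median was -0.19, or -0.04 without the host genes.

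Lists with fewer than 5 listed members were described by their genes alone. All 3 listed heat shock and oxidative stress genes of 39 were HSP70 genes and higher in the shALKBH5 library: HSPA1A, HSPA1B (2096 against 1112, 1.88-fold) and HSPA6 (5.96 against 0, at least 1.97-fold by the bound of 3 reads, exact lower limit 1.16-fold). Outside the fixed list, the HSP70 family genes HSPA1L (4.97 against 18.1, 3.65-fold) and HSPA12B (9.93 against 27.2, 2.74-fold) were lower, though HSPA12B was higher (0.08) under the rescaling to the listed genes' median. HSPA1A and HSPA1B are near-identical copies of each other, and HSPA6 has such a copy in HSPA7. Of 42 unfolded protein and amino acid stress genes 4 were listed. The stress-induced NUPR1 (29.8 against 5.03, 5.92-fold), ATF3 and the asparagine synthetase gene ASNS (138 against 70.5, 1.96-fold, uncertain for its near-identical copy AC079781.5) were higher, and CBS was lower. Both listed p53 and senescence genes of 32 were higher, the cell cycle inhibitor CDKN2B (495 against 249, 1.99-fold) and the kinase PLK3 (331 against 173, 1.91-fold). CDKN2B is overlapped on the opposite strand by CDKN2B-AS1, and PLK3 by TCTEX1D4.

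Among 54 angiogenesis and growth factor genes, the EGF receptor ligand HBEGF (515 against 220, 2.33-fold) and the receptor FGFR3 (1900 against 1060, 1.79-fold) were higher in the shALKBH5 library and PDGFD was lower (10.9 against 35.2, 3.22-fold). IL11, a cytokine of the interleukin-6 family, was the 1 listed gene of 46 in the NF-kB and cytokine list, at 2545 against 1284 (1.98-fold; interval 1.85 to 2.12). Of 38 proteases of invasion and their inhibitors, the collagenase MMP1 (5.96 against 0) and the serine protease inhibitor TFPI2 (1447 against 803, 1.80-fold) were higher, and the gelatinase MMP9 was lower (61.6 against 121, 1.96-fold), though higher (0.56) under the rescaling to the listed genes' median. TFPI2 and MMP9 are overlapped on the opposite strand by GNGT1 and SLC12A5-AS1. ITGA1, a collagen-binding integrin chain, was the 1 listed gene of 40 adhesion molecules and stood at 49.7 against 118, with its direction turned (0.28) under that rescaling. SNAI1 was the 1 listed gene of 29 in the epithelial-mesenchymal transition list. Both listed type I interferon response genes of 54 were lower, the antiviral GTPase MX1 at 4.97 against 26.2 (5.27-fold; 1.99 to 17.6) and OASL at 6.95 against 21.1 (3.04-fold; 1.24 to 8.47).

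Markers of cell identity were sparsely listed. Of 58 trophoblast markers CGB8, a chorionic gonadotropin beta gene, was listed at 23.8 against 7.05, with near-identical copies in CGB3 and CGB5. Stromal markers had 3 listed members of 22 (DCN, COL1A1 and COL1A2) and endothelial markers 1 of 13 (ESAM, 0.993 against 11.1). No member was listed of 9 lists: leukocyte markers, CCN family and YAP targets, TGF-beta and BMP response, hypoxia and glycolysis, cell cycle, cholesterol and fatty acid synthesis, ribosomal proteins, mitochondrially encoded messenger and ribosomal RNAs (a list without the transfer RNAs, of which MT-TN and MT-TC were listed) and housekeeping genes. Genes that missed the p-value limit and genes without reads are both absent from a selected list, so these 9 lists gave no level.

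**Figure D2:**
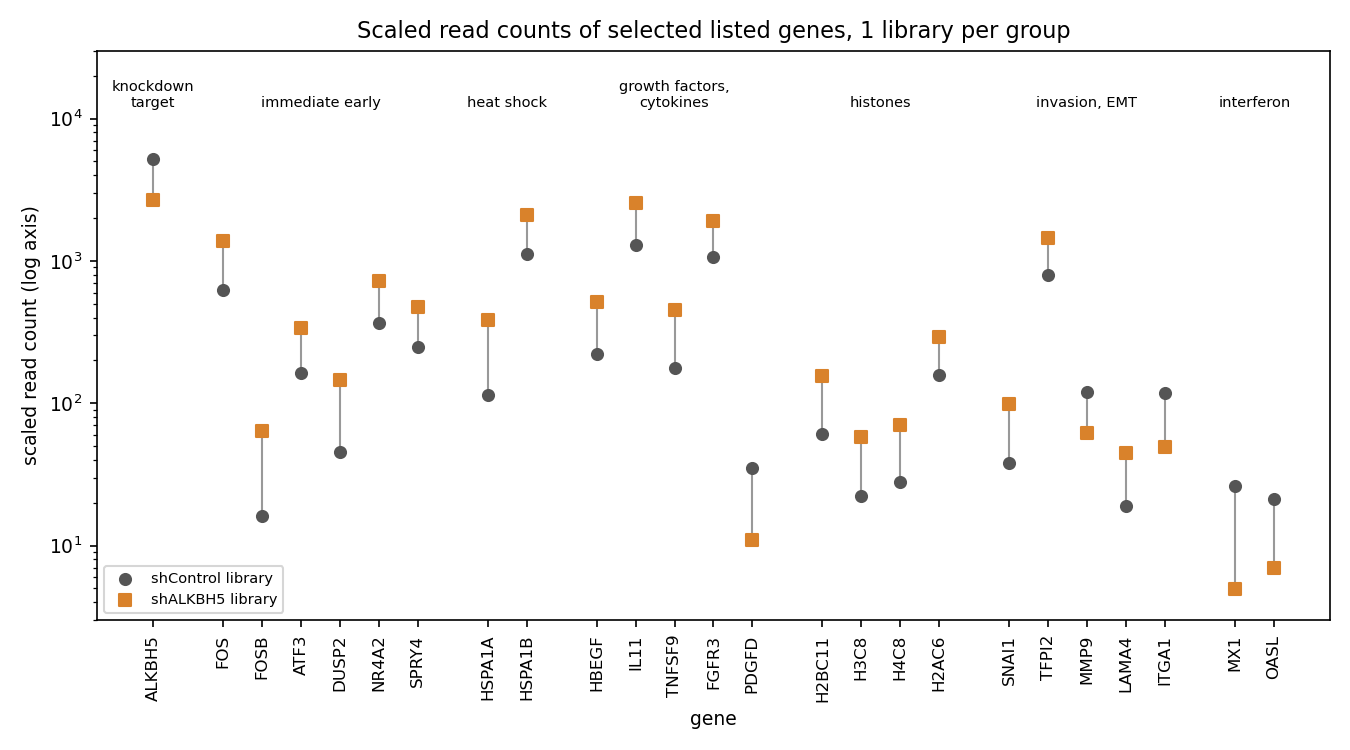
Scaled read counts of list members and TNFSF9 in the shControl (gray circles) and shALKBH5 (orange squares) libraries, 1 library each, on a log axis. The 6 immediate early genes, HSPA1A and HSPA1B stood higher in the shALKBH5 library, while ALKBH5, PDGFD, MMP9, ITGA1, MX1 and OASL stood lower. Of the lower genes, ALKBH5, MMP9 and ITGA1 turn under the rescaling to the listed genes' median, by the construction of that rescaling.

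The authors' deposited table listed 189 rows higher and 442 lower in shALKBH5, and 9 of the 631 had an adjusted p-value under 0.05 in the authors' deposited table. SERF1B (adjusted p 0.000669), SNORD3B-1 (0.000859) and MT-TN (0.0479) were the 3 higher ones in the authors' deposited table. BOLA2B (9.86e-09), COL1A2 (0.0201), the circadian repressor BHLHE41 (0.0241), CDK15 (0.0241), the unnamed gene ENSG00000279633 (0.0241) and the complement gene C4B (0.0479) were the 6 lower ones in the authors' deposited table. COL1A2 counts among the 6 as deposited, and its direction is uncertain because its values fall on the step of the opposite column. BHLHE41, which SSPN overlaps on the opposite strand, had 1.99 scaled counts against 35.2. C4B, whose near-identical copy is C4A, had 2.98 against 36.2. The p-values in the authors' deposited table matched an exact test at 1 fixed dispersion of 0.04 within 1% for 630 of the 631 rows, so they rest on a spread of 20% that was not measured between replicates.

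For 628 of the 631 rows (99.5%), both values were whole multiples of their own column's step within 0.01 reads. The steps were 0.993 for shALKBH5 and 1.007 for shControl. COL1A1, COL1A2 and SMAD5 were the 3 exceptions. Both values of COL1A1 and both of COL1A2 were whole on the step of the opposite column, and those of SMAD5 were whole on neither. For SMAD5, which encodes a transducer of bone morphogenetic protein signals, the log2 fold change in the authors' deposited table (-2.16) also differed from that of its columns (-2.40).

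**Figure D3:**
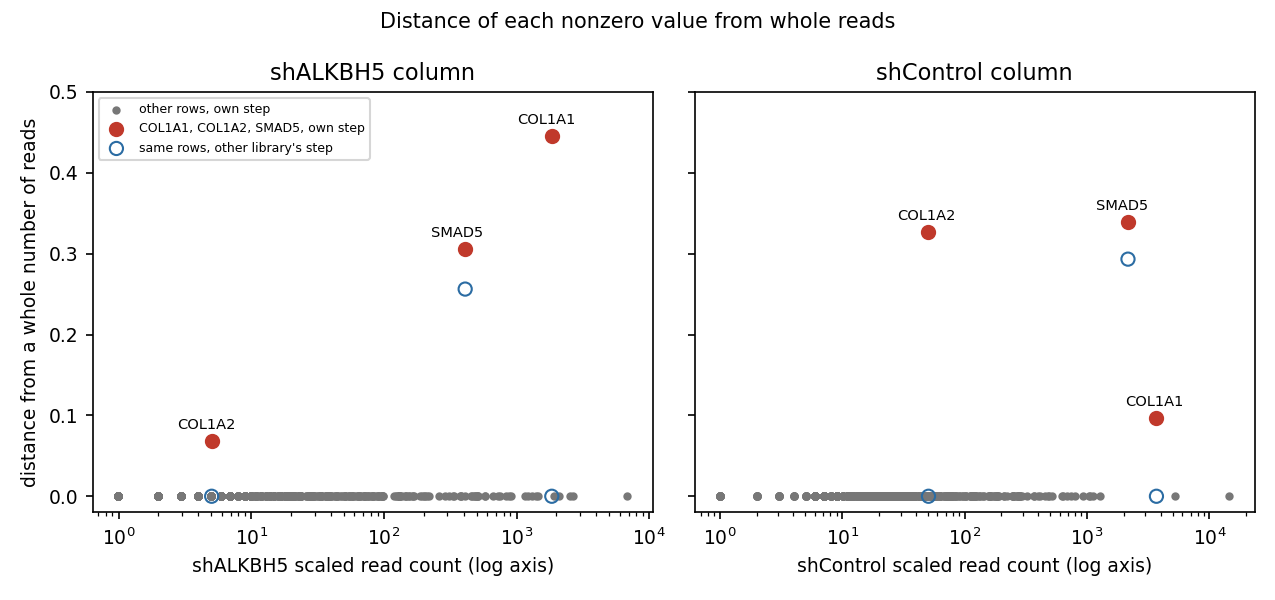
Distance of every nonzero value from a whole number of reads, for the shALKBH5 (left) and shControl (right) columns, against the scaled read count on a log axis. Gray points are other genes on their own column's step, red points are COL1A1, COL1A2 and SMAD5 on their own step and open blue circles are the same genes on the opposite library's step, where COL1A1 and COL1A2 fall to 0 and SMAD5 stays at 0.256 and 0.293.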

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

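Of 72 alternatives computed, 51 left a result the same, 18 moved it and 3 reversed its direction. Some of the 51 could not have differed, so the tally is no measure of robustness. Among these were floors that removed no gene, summed names that are in no list, and the exclusion of COL1A1, COL1A2 and SMAD5 from lists without them. The floor of 50, the exclusions of genes and the setting of genes at 0 to their bound were chosen after the data were seen, the others before. Rescaling the shALKBH5 column to a median log2 ratio of 0 over the listed genes reversed ALKBH5 (0.58) and the extracellular matrix median (0.53), and gave 176 genes at least 2-fold lower and medians of 2.63 for immediate early genes, 2.81 for histones and -0.19 for short non-coding RNAs. Equal upper quartiles gave -0.44 for ALKBH5, -0.49 for extracellular matrix, 1.61 for immediate early genes and 1.80 for histones. Both rescalings take their reference from the selected genes, so such turns follow from their construction and do not test for a scaling error. The median and upper-quartile rescalings placed 109 and 0 of the 439 lower genes on the higher side. Without COL1A1, COL1A2 and SMAD5 the extracellular matrix median was 1.18, because 2 of its 5 members were removed. A floor of 50 gave 43 genes at least 2-fold higher and 70 lower, and a threshold of 4-fold gave 72 and 228. At 4-fold or more, 87 of the 631 entries were higher and 253 lower by the folds of the authors' deposited table, and 38 and 149 without entries holding a 0, whose fold depends on the small number added to both values. Other pseudocounts, summed names and floors of 0 and 5 changed no direction, and the floors removed no gene, since the smallest larger value was 5.96. Rescaling to housekeeping genes was not run, with 0 of them listed. No paired analysis was possible because each group had 1 library, and for the same reason leaving out a library could not be tried. Library depth limits the low genes most: 13.2% of unchanged simulated genes passed 2-fold. That simulation held counting noise alone, without spread between libraries or selection by p-value, so the share in the selected list may be higher.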

Other observations

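The tests and the choice of genes in this part were made after the values were seen. Several abundant genes outside the fixed lists were higher in the shALKBH5 library. CTSD and CTSC, lysosomal proteases, stood at 1229 against 690 (1.78-fold) and 1311 against 734 (1.79-fold). SGK1, a serum- and glucocorticoid-regulated kinase, stood at 916 against 516, LTBR, the lymphotoxin beta receptor, at 1159 against 634, SAT1, which acetylates polyamines, at 664 against 371, and SCG2, a secretory granule protein, at 384 against 183 (2.10-fold). HAS3, a hyaluronan synthase, stood at 154 against 75.5. On the lower side were RNF150 (575 against 1028, 1.79-fold), ZNF470 (260 against 489), PLSCR4, a scramblase family member (212 against 401), RORA, an orphan nuclear receptor (86.4 against 210, 2.43-fold), and DLL1, a Notch ligand (75.5 against 168, 2.23-fold). RNF150, ZNF470, PLSCR4, RORA and DLL1 all turn to the higher side when rescaled to the listed genes' median, and no list was fixed for these genes. LTBR, HAS3, RORA and DLL1 overlap SCNN1A, CHTF8, RORA-AS1 and FAM120B on the opposite strand, and CTSD and SGK1 overlap other annotated genes, so their values share that uncertainty.

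By gene type, antisense genes had 31 higher and 63 lower, long intergenic non-coding RNAs 23 and 47, and processed pseudogenes 21 and 49, shares of 33.0%, 32.9% and 30.0% higher beside 26.3% for protein-coding genes. Both mitochondrial transfer RNA genes listed, MT-TN and MT-TC (310 against 122, 2.54-fold), were higher in the shALKBH5 library. They lie on the mitochondrial genome from 5657 to 5729 and from 5761 to 5826.

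The 9 genes under 0.05 after adjustment in the authors' deposited table hold 4 with a near-identical copy (44.4%, exact interval 13.7 to 78.8%), against 56 of the 614 other genes searched (9.12%, 6.96 to 11.7%). For the genes that have such a copy, reads divided differently between near-identical gene copies could be a source of the ratios of 4 of the 9, BOLA2B, SERF1B, SNORD3B-1 and C4B. For 1 of the 4, SNORD3B-1, the copy SNORD3A was listed and went the same way, which argues against a shift of reads between these genes alone. The other copy found for SNORD3B-1, AC007952.4, may be the unnamed listed gene ENSG00000262202, whose transcript also matches SNORD3B-1. Whether a copy of SNORD3B-1 is missing from the list was therefore not settled. For 3 the copy was not listed, so the test leaves this open for all 4. Reads divided differently between near-identical gene copies, as the cause for all 9 genes, is argued against by the 5 with no such copy, among them CDK15, BHLHE41 and MT-TN. An effect of the knockdown on any of the 9 remains open and untested, since hairpin and library cannot be separated with 1 library per group.

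COL1A1, COL1A2 and SMAD5 have values off the step of their columns. For COL1A1 and COL1A2 an exchange of the values of both columns is a candidate explanation: 4 of 4 values are whole on the opposite column's step, within 7.15e-06 reads, while on their own step the nearest lies 0.0679 reads away. Rounding or a drifting step is argued against by 0 of 231 other values of at least 50 lying off their own step. If the values were exchanged, both collagen genes would be higher in the shALKBH5 library, opposite to the deposited direction. SMAD5 differs, since a value 0.293 reads from whole on the opposite step argues against a plain exchange, and its p-value of 0.0142 in the authors' deposited table stands against 4.35e-08 from its columns at the fixed dispersion, which leaves the origin of its values open.

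The direction of listed genes differed with abundance: 30 of 42 genes with a mean above 200 were higher in the shALKBH5 library (71.4%, exact interval 55.4 to 84.3%), against 158 of 585 at or below it (27.0%, 23.4 to 30.8%). A single scaling error between the libraries, as the whole cause, would tilt abundant and sparse genes the same way. The 71.4% of abundant genes that were higher argue against it. That share is the pattern itself and not a separate test. An even background of reads, such as genomic DNA in the shControl library, could supply at most 14.8% of the 9357 excess scaled reads of the 427 lower sparse genes, a bound set by DCN at 0 in that library. Gene length as the whole cause is argued against by genes of at least the median length of 1974 bases. Of these, 71.4% were higher above a mean of 200 (25 of 35, 53.7 to 85.4%) and 16.5% at or below it (46 of 279, 12.3 to 21.4%). COL1A1 and SMAD5, of uncertain direction, are among the lower genes of the 42 and of the 35. Turning either would raise both shares of 71.4%. An effect of the knockdown, gene length or a background in part and other library differences may each underlie the lean and were not separated by this design.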
